A study of Bos taurus with 4 samples.

How the data were processed

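Nuclei isolated from fresh bovine placenta were measured by 10x Genomics single-nucleus RNA sequencing in 4 samples, 2 of the cotyledon and 2 of the intercotyledonary placenta. The values are raw UMI counts per gene and barcode, deposited by the authors with no normalization and with every barcode kept, 6794880 per sample. The genome was ARS-UCD 1.2 per the submitters' processing notes. The notes name Cell Ranger 2.1.1 and the matrix header names version 4, so the version is not settled, and whether intronic reads were counted is not given in the sources used here. The files hold 27270 genes, of which 6922 have no symbol.

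Barcodes were kept as nuclei with at least 1000 UMIs and 500 genes. A limit of 5% on mitochondrial UMIs was planned before the data were examined, but it left 613 and 2190 barcodes in cotyledon replicates 1 and 2 and 5 and 390 in intercotyledonary replicates 1 and 2. It was therefore replaced, after these totals were seen and before any comparison was made, by a limit for each sample at 0.5 of the mitochondrial share of its own free RNA. The free RNA profile came from barcodes with at least 200 UMIs and fewer genes than the median of such barcodes, and the share from the 13 mitochondrial genes with a symbol. The limits were 17.8%, 9.42%, 27.7% and 14.2%, in the order cotyledon replicates 1 and 2 and intercotyledonary replicates 1 and 2. The 37 mitochondrial genes were then left out of all comparisons. With every mitochondrial UMI taken as free RNA, free RNA made up an estimated 7.4%, 12.6%, 5.31% and 4.5% of the other UMIs of the nuclei.

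Scrublet, run in Scanpy 1.11.5, marked 0, 3, 9 and 5 barcodes at its own threshold. Barcodes of the highest score were instead removed at the planned rate of 0.8% per 1000 barcodes, which took out 596, 177, 41 and 23. The kept nuclei numbered 8034, 4525, 2228 and 1664, in all 16451, and held 32434330, 65941348, 17391013 and 25881446 UMIs.

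Nuclei were clustered with Seurat 5.3.0 on log-normalized counts, 2000 variable genes, 30 principal components, RPCA integration over the 4 samples and Louvain clustering at resolution 0.5. The 264 symbols of the fixed gene lists were left out of the variable genes, which left 1863. Markers were fixed before the data were examined, and the naming thresholds that follow were set with the data in hand. A cluster took the name of another cell type with at least 3 of its markers raised 5-fold over other nuclei and detected in 10% of its nuclei, 1 of them among its 10 leading genes, of binucleate-like trophoblast with at least 3 binucleate markers raised 2-fold and either 1 of them among its 10 leading genes or 0.5 of the markers raised, and of uninucleate-like trophoblast with at least 3 trophoblast markers raised 3-fold over the other cell types. A cluster with more markers of another list than of its own among its 10 leading genes stayed unnamed, as did one with no marker of its own there and a median depth, relative to that of each sample, under 0.33. Free RNA was judged from the levels in the endothelium-like, macrophage-like and lymphocyte-like nuclei, pooled within each sample, or by tissue where a single value is given for a tissue.

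Raw UMI counts were summed per sample over all nuclei, over the binucleate-like and over the uninucleate-like nuclei. Each tissue comparison set 2 cotyledon against 2 intercotyledonary samples by the two-sided quasi-likelihood test of edgeR 4.0.16, with TMM scaling, edgeR's filter on low counts and Benjamini-Hochberg adjustment at 0.05. The interaction of tissue and trophoblast class, and the difference between the classes, used the 8 sums of 4 samples and 2 classes with the sample as a block. The difference between classes was adjusted over the tested genes of the fixed lists only, since other genes helped to define the classes. Shares of nuclei were compared by an exact two-sided permutation test. The 15 gene lists and 10 marker lists were tested with camera in limma 3.58.1 on voom values. This was done at a preset correlation of 0.01 and again with the correlation estimated, for lists with at least 5 tested members. Benjamini-Hochberg adjustment was made over the lists. At the preset correlation camera sets the genes of a list against other genes, so genes and not samples are its units. With the correlation estimated it has only the few residual degrees of freedom that the samples leave. A list can therefore lose its call there whatever its correlation.

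Genes were named by a rule written before the data were examined. In each tissue comparison it took the 10 genes of largest fold each way that had a symbol, passed the test, averaged at least 10 CPM over the 4 samples and had both samples of 1 tissue above both of the other. From each list it took up to 4 called members by mean expression, or 2 where none passed. Between the classes it took up to 4 called members of each list by fold. A few further genes were named after their values were seen, as leading genes of clusters. Ratios with 0 counts in a tissue are given as a bound against a floor of 3 counts, and those with 1 to 3 counts with a 95% counting interval.

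The tests were tested on simulated data, in which 200 of the tested genes were changed at a dispersion of 0.05, and fewer in the comparison between classes, where 223 were tested. A 4-fold change was found for 96% of genes over all nuclei, 87.5% in binucleate-like and 96.7% in uninucleate-like trophoblast and 45.6% in the interaction, and a 2-fold change for 14%, 13.2%, 17.9% and 4.3%. Between the classes all 4-fold and 88.6% of 2-fold changes were found. False calls were 6 of 116, 2 of 93, 4 of 111, 2 of 53 and 1 of 71, in the same order. These rates hold only for that dispersion, which was the same in every comparison. In the data, log2 differences between the 2 samples of a tissue had an SD over genes of 0.906 (cotyledon) and 0.972 (intercotyledonary) over all nuclei. The rates may therefore overstate what the tests find here.

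Alternatives were DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, the replicate number as a block, each sample left out in turn, counts thinned to the smallest sum, a minimum of 2000 UMIs, a minimum set per sample, no doublet removal, no integration, resolution 0.2 and no sample block. Alternatives added after the data were seen were a mitochondrial limit at 0.25 of the free RNA share, the planned mitochondrial limit, the free RNA profile subtracted, single clusters within the 2 trophoblast classes, and all nuclei without the epithelium-like class. Mesenchyme-like nuclei and the other small classes were not tested gene by gene between tissues, because at least 1 sample had fewer than 30 of them. Further work used R 4.3.3, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.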

Results

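Single-nucleus RNA sequencing was done on 4 samples of bovine placenta, 2 of the cotyledon and 2 of the intercotyledonary placenta. Cotyledons are the fetal patches of villi that join the caruncles of the uterus, and the intercotyledonary placenta is the smooth membrane between them. The deposited matrices held every barcode, with 123240728 and 200642849 UMIs in cotyledon replicates 1 and 2 and 250043883 and 176146375 in intercotyledonary replicates 1 and 2. After barcodes without a nucleus and doublets were left out, these samples kept 8034, 4525, 2228 and 1664 nuclei. The median depth of a nucleus was 2617.5, 8247, 6974 and 9344 UMIs, in the same order, with 1374, 2746, 2341 and 2752 genes detected. Nothing in the labels says that the replicates are separate animals, so the p-values of single genes measure only the spread between these samples, which may be technical. The camera p-values of gene lists at the preset correlation set the genes of a list against other genes. They do not measure how far a list would vary between samples. X inactivation could not be described, since the gene XIST is not among the 27270 genes of the files.

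Over the 4 samples together, most nuclei were named trophoblast-like, trophoblast being the fetal epithelium of the placenta. The nuclei fell into 19 clusters, and markers fixed before the data were examined named 7 classes. Binucleate-like trophoblast carried genes of the placental lactogen and pregnancy-associated glycoprotein (PAG) families, the hormones and secreted proteins of the binucleate cells that fuse with the uterine epithelium. In cotyledon replicates 1 and 2 this class held 11.2% (95% exact Clopper-Pearson interval 10.5 to 11.9%) and 24.2% (22.9 to 25.4%) of the nuclei, and in intercotyledonary replicates 1 and 2 it held 10.1% (8.92 to 11.5%) and 4.87% (3.88 to 6.01%). These intervals cover counting error only. Uninucleate-like trophoblast was the main class, with 69.7%, 42.6%, 71.5% and 42.8% of the nuclei in the same order. Endothelium-like nuclei made up 6.04%, 2.56%, 0.628% and 1.26%, and macrophage-like and lymphocyte-like nuclei at most 3.19% of any sample. An allantoic or amniotic epithelium-like cluster, led by TNC, KRT17, LY6D and UPK3BL1, took 6.24% and 36.8% of the intercotyledonary nuclei but 0.112% and 0.066% of the cotyledon nuclei. It carried 3 raised markers of its own list and 9 raised trophoblast markers, so its name is uncertain. Raised trophoblast markers thus do not by themselves tell uninucleate-like trophoblast from other epithelium. Cluster 0, the largest of that class, carried 10 of them, but 0 were among its 10 leading genes, nor were any in the other clusters of the class. Unnamed clusters held 9.46%, 28.6%, 9.61% and 7.33% of the nuclei. One of them, with 3.87%, 17.9%, 0.539% and 0.12%, was kept out of a class by a threshold set after the data were seen. The naming rule, also set with the data in hand, kept out 2 more that carried 9 and 11 raised trophoblast markers. Cluster 7, with an epithelium marker among its leading genes, held 4.79%, 6.39%, 2.38% and 1.2%, and cluster 12, of low depth, held 0.299%, 3.74%, 4.58% and 4.39%.

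The shares describe how nuclei were assigned and are not a test of composition, because genes that lead the clusters differ between the tissues and the samples differ in depth. The mean share of binucleate-like trophoblast was 17.7% ± 9.18 (SD, n = 2) in the cotyledon and 7.51% ± 3.73 in the intercotyledonary placenta. At resolution 0.2 the direction turned, with means of 14.177% and 15.975%. The mean share of the epithelium-like class was 0.089% ± 0.032 against 21.5% ± 21.6. With 2 samples against 2, the smallest p that the exact two-sided permutation test can give is 0.33, so no difference in share could pass.

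**Figure D1:**
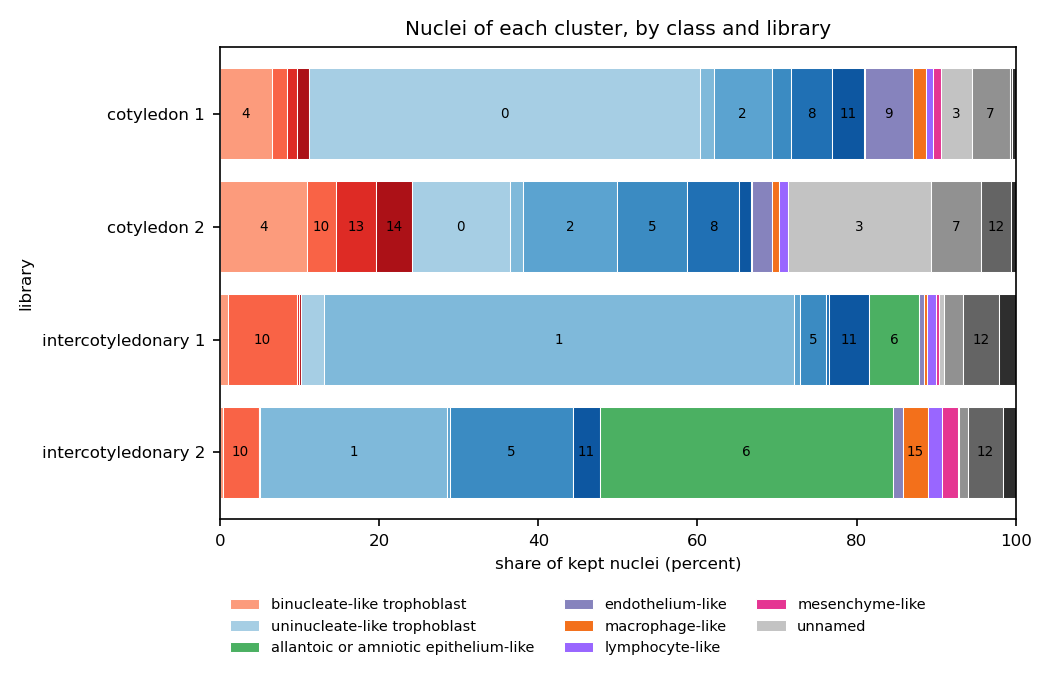
Share of the kept nuclei (percent, horizontal axis) that each cluster took in each of the 4 samples (vertical axis), coloured by class and numbered by cluster where it held over 3%. The uninucleate-like class lay mostly in cluster 0 in cotyledon replicate 1 and in cluster 1 in the intercotyledonary samples, and was spread over several clusters in cotyledon replicate 2, and the epithelium-like class was seen almost wholly in the intercotyledonary samples.

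Over all nuclei, 4 of 5 ancient PAGs, 9 of 16 interferon-stimulated genes, 9 of 11 major histocompatibility complex (MHC) class I genes and 15 of 20 stress genes were higher in the intercotyledonary placenta, and 9 of 20 S phase and 5 of 20 G2 and M phase genes were higher in the cotyledon. PAG11 (ENSBTAG00000022759), a member of the older branch of the PAG family, averaged 24.9 ± 21.5 CPM (UMIs scaled to a common library total, mean ± SD, n = 2 per tissue) in the cotyledon and 18261 ± 2264 in the intercotyledonary placenta. CDKN1C (ENSBTAG00000031184), an imprinted inhibitor of the cell cycle, averaged 319 ± 19.4 against 2990 ± 375 CPM, and the imprinted growth regulator PHLDA2 (ENSBTAG00000031194) 953 ± 43.9 against 6402 ± 418. MX1 (ENSBTAG00000030913), an antiviral protein induced by interferon, averaged 3.24 ± 3.04 against 156 ± 65.6 CPM. The replication helicase subunit MCM5 was higher in the cotyledon, at 115 ± 40.1 against 20.5 ± 0.563 CPM.

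By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2212 of 14077 genes differed over all nuclei, 670 higher in the cotyledon and 1542 higher in the intercotyledonary placenta. The count rested on the cotyledon pair: it was 790 without cotyledon replicate 1 and 346 without cotyledon replicate 2. The split moved to 33 and 313 without cotyledon replicate 2, to 87 and 895 with a mitochondrial limit at 0.25 of the free RNA share and to 1641 and 2411 with no filter on low counts. No gene passed with the mitochondrial limit planned before the data were examined, which left 5 barcodes in intercotyledonary replicate 1. There edgeR gave 1540 genes at an unadjusted p under 0.05, and DESeq2 was not run at that limit. In this and the other tissue comparisons, each named gene that passed had both samples of 1 tissue above both of the other, a separation that chance alone gives for 33.3% of genes. The largest differences towards the intercotyledonary placenta included LAMP5, a lysosomal membrane protein (2 UMIs in the cotyledon, a ratio of 1466 with a 95% counting interval of 405 to 12120, edgeR Benjamini-Hochberg adjusted p = 0.00297), and the amino acid transporter gene SLC7A4 (log2 ratio of cotyledon over intercotyledonary -10.07 ± 1.39 SE, adjusted p = 0.00942). LY6D, KRT17, UPK3BL1 and TNC were also among them, and these lead the epithelium-like cluster. Without its nuclei TNC had a log2 ratio of -7.53 (edgeR Benjamini-Hochberg adjusted p = 0.00446) beside -10.93 with them. Among the largest differences towards the cotyledon was CDX1, a caudal-type homeobox gene, at 29.0 ± 21.3 against 0.422 ± 0.542 CPM (log2 ratio 5.98 ± 1.23, edgeR Benjamini-Hochberg adjusted p = 0.0271). Its adjusted p was 0.128 without cotyledon replicate 2 and reached 0.308 over the 16 alternatives tried. CDX1 is a leading gene of binucleate-like cluster 14, with 3.04% of the cotyledon and 0.112% of the intercotyledonary nuclei on average.

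Among the fixed lists over all nuclei, 15 of the 20 handling stress and immediate early genes were higher in the intercotyledonary placenta and 5 did not pass (17 adjusted over the list alone, camera, preset correlation, adjusted p = 1.53e-11, and adjusted p = 0.35 with an estimated correlation). JUN, a subunit of the immediate early transcription factor AP-1, averaged 428 ± 54.1 against 3304 ± 668 CPM. The interferon-stimulated genes had 9 of 16 higher there (14 adjusted over the list alone, adjusted p = 1.846e-07, and adjusted p = 0.472 with an estimated correlation). MHC class I had 9 of 11 (10 adjusted over the list alone, adjusted p = 2.848e-06, and adjusted p = 0.472 with an estimated correlation). Of the ancient PAGs 4 of 5 were higher there, with adjusted p = 0.000282 (4 adjusted over the list alone, and adjusted p = 0.427 with an estimated correlation). The pan-trophoblast markers had 4 of 12 higher there (6 adjusted over the list alone, adjusted p = 0.000166, and adjusted p = 0.427 with an estimated correlation). S phase genes were the clearest list towards the cotyledon, with 9 of 20 higher and 11 not passing (16 adjusted over the list alone, adjusted p = 1.846e-07, and adjusted p = 0.472 with an estimated correlation). Genes of G2 and M phase had 5 of 20 higher in the cotyledon (10 adjusted over the list alone, with 1 lower, adjusted p = 0.000166, and adjusted p = 0.548 with an estimated correlation). MCM5 lost its call without cotyledon replicate 2 (edgeR Benjamini-Hochberg adjusted p = 0.0752, with 0.282 the highest over the 16 alternatives).

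Genes of the extracellular matrix went mostly the same way over all nuclei, with 11 of 26 higher in the intercotyledonary placenta and 2 higher in the cotyledon (14 and 3 adjusted over the list alone, camera adjusted p = 0.000281, and adjusted p = 0.477 with an estimated correlation). TIMP3, an inhibitor of matrix proteases, averaged 4.94 ± 3.7 against 163 ± 6.82 CPM. Transporters had 11 of 29 higher there and 3 higher in the cotyledon (15 and 5 adjusted over the list alone, adjusted p = 0.00445, and adjusted p = 0.43 with an estimated correlation). Imprinted and insulin-like growth factor genes had 8 of 21 higher there and 1 higher in the cotyledon (8 and 2 adjusted over the list alone, adjusted p = 0.0102, and adjusted p = 0.504 with an estimated correlation). The imprinted list's adjusted p was 0.141 without the epithelium-like nuclei. Prostaglandin genes had 5 of 12 higher there and 1 higher in the cotyledon (7 and 1 adjusted over the list alone, adjusted p = 0.0142, and adjusted p = 0.472 with an estimated correlation). PLA2G4A, the phospholipase that frees arachidonic acid, averaged 0.898 ± 0.648 against 23.4 ± 9.37 CPM. Of the steroid synthesis genes 1 of 16 was higher there and 2 higher in the cotyledon, of the trophoblast transcription factors 3 of 19 each way, and of the angiogenesis and hypoxia genes 2 of 18 there and 1 in the cotyledon. Camera called none of these 3 lists, with adjusted p of 0.804, 0.923 and 0.256. Both trophoblast Kunitz domain protein genes tested, of 3 in the files, were higher in the intercotyledonary placenta.

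Markers of the other cell types also moved over all nuclei. Of the mesenchyme markers 3 of 9 were higher in the intercotyledonary placenta (6 adjusted over the list alone, camera adjusted p = 0.000686, and adjusted p = 0.504 with an estimated correlation), of the macrophage markers 2 of 10 (3 adjusted over the list alone, adjusted p = 0.00998, and adjusted p = 0.555 with an estimated correlation), and of the lymphocyte markers 1 of 8 (2 adjusted over the list alone, adjusted p = 0.0132, and adjusted p = 0.504 with an estimated correlation). None of the 10 endothelium markers passed on its own by edgeR, with 5 higher in the cotyledon adjusted over the list alone and adjusted p = 0.0298 for the list (adjusted p = 0.669 with an estimated correlation, and 0.0717 without the epithelium-like nuclei). Of the epithelium markers 3 of 5 were higher in the intercotyledonary placenta, of the pericyte markers 1 of 5 there, of the binucleate markers 7 of 23 in the cotyledon and 5 there, and of the erythroid markers 1 of 3 in the cotyledon. None of the 7 endometrium markers passed, with HOXA11 at 6.01 ± 2.79 against 1.35 ± 0.28 CPM.

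In binucleate-like trophoblast, most genes that differed were higher in the intercotyledonary placenta. The cytokine IL6 (ENSBTAG00000014921) averaged 8708 ± 1140 CPM there and 22.0 ± 13.3 CPM in the cotyledon. TFPI (ENSBTAG00000049919), an inhibitor of the tissue factor pathway of coagulation, averaged 5018 ± 1930 against 15.4 ± 2.77 CPM, and the protease inhibitor TIMP2 (ENSBTAG00000010899) 4591 ± 256 against 542 ± 82.8. PAG10 (ENSBTAG00000004116), an ancient PAG, averaged 25685 ± 3065 against 88.2 ± 45.5 CPM, and the prolactin-related gene PRP-VII 615 ± 15.7 against 0.466 ± 0.371. PDCD1 (ENSBTAG00000011543), an immune checkpoint receptor, was among the genes higher in the cotyledon, at 62.6 ± 56.9 against 0.518 ± 0.733 CPM, which rests on 2 intercotyledonary UMIs (ratio 138, 95% counting interval 38.2 to 1139).

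Of 10123 genes tested in this class, 665 differed by edgeR with Benjamini-Hochberg adjustment, 65 higher in the cotyledon and 600 higher in the intercotyledonary placenta. The split was 626 and 840 without intercotyledonary replicate 1, 492 and 816 at resolution 0.2, 472 and 926 with no filter on low counts, 268 and 717 without integration, 202 and 361 within cluster 10, and 8 and 251 without cotyledon replicate 2. The count was 347 without cotyledon replicate 1, 259 without cotyledon replicate 2 and 1466 without intercotyledonary replicate 1. Cluster 4 held 51.1% of the class in the cotyledon and 9.45% in the intercotyledonary placenta, cluster 10 held 15.8% and 87.6%, and clusters 13 and 14 held 16.6% and 16.5% of the cotyledon nuclei but 1.3% and 1.63% of the intercotyledonary ones. Cluster 10 carried 22 raised binucleate markers but 0 raised trophoblast markers, while clusters 4, 13 and 14 carried 6, 6 and 4 of the latter. Its median depth relative to that of each sample was 0.632, beside 4.687, 2.035 and 7.154. The tissue comparison may therefore set unlike cells against each other. PDCD1 and SLC6A6 are leading genes of cluster 13, and within cluster 10 PDCD1 had a log2 ratio of 5.48 (edgeR Benjamini-Hochberg adjusted p = 0.00201) and SLC6A6 of -0.305 (0.726), so the difference of SLC6A6 was not seen there. Cluster 14 had a median of 44356 UMIs, so doublets are to be weighed there, and with no doublets removed 692 genes passed. IL6, TFPI and PAG10 lead cluster 10, but each also differed within that cluster, where the log2 ratio of cotyledon over intercotyledonary was -7.94, -6.68 and -9.35 (edgeR Benjamini-Hochberg adjusted p = 0.000241, 0.000241 and 0.000273). Over the class their log2 ratios were -9.19 ± 0.63, -8.92 ± 0.5 and -8.8 ± 0.57 (SE), and their highest adjusted p over 17 alternatives was 0.00253. PAG11 stood at 656.3 and 675.2 CPM in binucleate-like nuclei of intercotyledonary replicates 1 and 2, beside 3603 and 407.5 CPM in the pooled endothelium-like, macrophage-like and lymphocyte-like nuclei. It lay below the pooled level in the first and above it in the second, so whether its counts are free RNA is open. ATP6V1G3, the largest difference towards the cotyledon, stood at 34.39 and 9.444 CPM in cotyledon replicates 1 and 2 beside 247.4 and 16.7 in those pooled nuclei, and is read as background.

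The binucleate markers themselves moved, with 11 of 23 higher in the intercotyledonary placenta and none higher in the cotyledon by edgeR (12 and 2 adjusted over the list alone, camera adjusted p = 1.328e-08, and adjusted p = 0.244 with an estimated correlation). These genes named the class, and members of the PAG and prolactin-related families are near copies whose counts may be shared, so their levels are uncertain. PRP9 averaged 1.68 ± 0.0715 against 9806 ± 1297 CPM and PRP1 1813 ± 22.1 against 19828 ± 639. Of the ancient PAGs 4 of 5 were higher in the intercotyledonary placenta (4, and 1 higher in the cotyledon, adjusted over the list alone, adjusted p = 2.222e-06, and adjusted p = 0.244 with an estimated correlation). PAG11 is 1 of the 4 although its counts may be free RNA. In intercotyledonary replicates 1 and 2, PAG12, of the same list, stood at 8.806 and 13.07 CPM in this class. The pooled endothelium-like, macrophage-like and lymphocyte-like nuclei stood at 29.53 (counting interval 9.588 to 68.91) and 8.67 (3.182 to 18.87). PAG12 is therefore read as background there. PAG8 stood at 305.1 and 546 CPM beside 1004 and 237, so it is as open as PAG11. PAG10 lay above the pooled nuclei in both samples, at 27850 and 23520 CPM beside 2923 and 345.4. With the free RNA profile subtracted fewer than 5 members were left, too few for the list test.

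Stress and immediate early genes also stood higher in intercotyledonary binucleate-like nuclei, with 10 of 18 passing (14 adjusted over the list alone, camera adjusted p = 2.022e-11, and adjusted p = 0.244 with an estimated correlation). The immediate early gene EGR1 averaged 33.8 ± 3.22 against 238 ± 110 CPM. Of the angiogenesis and hypoxia genes 6 of 14 were higher there (10, and 1 higher in the cotyledon, adjusted over the list alone, adjusted p = 0.000151, and adjusted p = 0.244 with an estimated correlation). PGF, placental growth factor, had 0 UMIs in the cotyledon nuclei of the class and 10.3 ± 2.26 CPM in the intercotyledonary ones, at least 160-fold higher against a floor of 3 counts over the group. Of the transporters 9 of 26 were higher in the intercotyledonary placenta and 1 in the cotyledon (11 and 4 adjusted over the list alone, adjusted p = 0.00185, and adjusted p = 0.244 with an estimated correlation). The calcium-binding protein S100G (ENSBTAG00000017020) averaged 12577 ± 660 against 46906 ± 3166 CPM, but within cluster 10 its edgeR Benjamini-Hochberg adjusted p was 0.555, the highest over 17 alternatives. STAR, which carries cholesterol into mitochondria for steroid synthesis, averaged 7.15 ± 3.42 against 92.3 ± 23.5 CPM, while its list had 1 of 14 higher each way and no call (adjusted p = 0.952).

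MHC class I had 3 of 5 genes higher in intercotyledonary binucleate-like nuclei (3 adjusted over the list alone, camera adjusted p = 0.000377, and adjusted p = 0.244 with an estimated correlation), extracellular matrix genes 6 of 14 (7 adjusted over the list alone, adjusted p = 0.00215, and adjusted p = 0.244 with an estimated correlation), and imprinted and insulin-like growth factor genes 4 of 17 (6, and 1 higher in the cotyledon, adjusted over the list alone, adjusted p = 0.0414, and adjusted p = 0.244 with an estimated correlation). The imprinted list lost its call with the free RNA profile subtracted (adjusted p = 0.851) and within cluster 10 (0.498). G2 and M phase genes leaned to the cotyledon with 1 of 20 passing (none by edgeR adjusted over the list alone, adjusted p = 0.00128, and adjusted p = 0.244 with an estimated correlation). S phase genes leaned the same way with none of 19 passing by edgeR (adjusted p = 0.0153, adjusted p = 0.363 within cluster 10, and adjusted p = 0.244 with an estimated correlation). MCM7 stood at 1136 ± 166 against 1055 ± 296 CPM. Of the mesenchyme markers 1 of 5 was higher in the intercotyledonary placenta (4, and 1 higher in the cotyledon, adjusted over the list alone, adjusted p = 0.00521, and adjusted p = 0.244 with an estimated correlation), a list with too few members left to test after the free RNA profile was subtracted or within cluster 10. Lists without a call were the transcription factors with 3 of 18 higher there (adjusted p = 0.403), the pan-trophoblast markers with 3 of 12 (0.0759), the interferon-stimulated genes with 1 of 7 (0.453) and the prostaglandin genes with 1 of 8 (0.494). Of the macrophage markers 1 of 2 was higher there, and none of the 3 erythroid, 2 endometrium and 1 epithelium markers tested passed by edgeR.

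In uninucleate-like trophoblast, the ancient PAGs PAG11 and PAG8, the calcium-binding protein S100G and genes of interferon response and antigen presentation such as B2M were higher in the intercotyledonary placenta. PAG11 averaged 47.9 ± 34.9 CPM in the cotyledon and 26329 ± 2159 in the intercotyledonary placenta, and PAG8 (ENSBTAG00000019226) 288 ± 215 against 11100 ± 6113. S100G averaged 4400 ± 1560 against 41849 ± 6843 CPM, and B2M (ENSBTAG00000012330), the light chain of MHC class I, 444 ± 100 against 4787 ± 2000. Higher in the cotyledon were GCM1 (ENSBTAG00000008148), a transcription factor of trophoblast differentiation, at 52.8 ± 25.9 against 3.94 ± 1.75 CPM, and CYP19A1 (ENSBTAG00000014890), the aromatase that makes oestrogens, at 10.8 ± 0.199 against 0.634 ± 0.151.

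By edgeR with Benjamini-Hochberg adjustment, 2957 of 12530 genes differed in this class, 1126 higher in the cotyledon and 1831 higher in the intercotyledonary placenta. The clusters behind the class differed between tissues. In cotyledon replicates 1 and 2, 70.5% and 28.8% of its nuclei were in cluster 0, 10.4% and 27.5% in cluster 2 and 2.46% and 3.94% in cluster 1. The leading genes of cluster 0 include ATP6V1G3 and others of proton and chloride transport, beside genes such as TLDC2 and HMX2. In intercotyledonary replicates 1 and 2, 82.7% and 54.8% were in cluster 1, led by PAG11, ADAM28 and FUT6, and 4.15% and 0.42% in cluster 0. Cluster 8, led by genes that include GJB5 and CYP19A1, held 9.39% of the class in the cotyledon and 0.43% in the intercotyledonary placenta. Both genes also differed within cluster 1, by log2 ratios of 8.55 and 5.75 (edgeR Benjamini-Hochberg adjusted p = 0.000215 and 0.000399). Within cluster 1 alone 1306 genes passed and within the cycling cluster 11 alone 1851, both chosen after the data were seen. PAG11, PAG8 and ADAM28 also differed within cluster 1, by log2 ratios of -5.11, -3.15 and -5.92 (edgeR Benjamini-Hochberg adjusted p = 0.00657, 0.00297 and 0.00461). All are leading genes of cluster 1, which held 138 and 76 cotyledon and 1316 and 391 intercotyledonary nuclei. Cluster 1 may join unlike cells of the 2 tissues, so differences within it do not exclude the make-up of the class as the cause. Over the class PAG11 had a log2 ratio of -9.61 ± 0.74 (SE), PAG8 -5.7 ± 0.79 and ADAM28 -10.79 ± 1.54, with a highest edgeR Benjamini-Hochberg adjusted p over 18 alternatives of 0.00657, 0.0268 and 0.00864. LY6D and KRT17 lead the epithelium-like cluster and stood at 60.42 and 217.9 CPM in the class in intercotyledonary replicate 2, beside 59.25 (95% counting interval 42.52 to 80.38) and 159 (130.6 to 191.6) in the pooled endothelium-like, macrophage-like and lymphocyte-like nuclei. In replicate 1 they stood at 5.553 and 18.51 CPM, under the limit of 21.79 that 0 UMIs in the pooled nuclei allow, so free RNA is not ruled out for LY6D, and KRT17 lay above the pooled level in replicate 2.

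The largest differences towards the cotyledon in this class included the gap junction gene GJB5, at 45.7 ± 39.2 against 0.379 ± 0.117 CPM (log2 ratio 6.45 ± 0.9 SE, edgeR Benjamini-Hochberg adjusted p = 0.0047), and ABCC2, an exporter of organic anions, at 21.8 ± 3.54 against 0.074 ± 0.105. ABCC2 rested on 2 intercotyledonary UMIs, a ratio of 318 with a 95% counting interval of 87.8 to 2632. Towards the intercotyledonary placenta, the fucosyltransferase FUT6 averaged 0.576 ± 0.814 against 334 ± 30.9 CPM, and STRA6, a receptor for retinol-binding protein, 0.0863 ± 0.122 against 70.3 ± 31.5. STRA6 rested on 3 cotyledon UMIs, a ratio of 961 with a counting interval of 328 to 4665.

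Stress and immediate early genes were higher in intercotyledonary uninucleate-like nuclei in 15 of 18 cases (17 adjusted over the list alone, camera adjusted p = 7.828e-12, and adjusted p = 0.272 with an estimated correlation), with JUN at 504 ± 66.1 against 3026 ± 133 CPM. Interferon-stimulated genes were higher in 12 of 16 (14 adjusted over the list alone, adjusted p = 2.863e-07, and adjusted p = 0.272 with an estimated correlation). MX1 averaged 3.66 ± 3.69 against 212 ± 47.9 CPM, but within cluster 1 its edgeR Benjamini-Hochberg adjusted p was 0.102, the highest over 18 alternatives. MHC class I genes were higher in 9 of 11 (10 adjusted over the list alone, adjusted p = 2.863e-07, and adjusted p = 0.272 with an estimated correlation), and TAPBP, which loads peptides on MHC class I, averaged 63.8 ± 2.49 against 294 ± 4.22 CPM. Ancient PAGs were higher in 4 of 5 (4 adjusted over the list alone, adjusted p = 0.001, and adjusted p = 0.272 with an estimated correlation). With the free RNA profile subtracted the list's adjusted p was 0.0998. PAG10, 1 of the 4, then had 0 UMIs in the intercotyledonary nuclei and turned to the cotyledon, at least 129-fold higher there against a floor of 3 counts (edgeR Benjamini-Hochberg adjusted p = 0.00535). It stood at 1467 and 371.7 CPM in intercotyledonary replicates 1 and 2, beside 2923 and 345.4 (303 to 392) in the pooled other cell types, and is read as background. Extracellular matrix genes were higher in 14 of 24 and lower in 2 (14 and 2 adjusted over the list alone, adjusted p = 0.000175, and adjusted p = 0.366 with an estimated correlation). Of the pan-trophoblast markers, which named the class, 7 of 12 were higher there and 1 in the cotyledon (10 and 1 adjusted over the list alone, adjusted p = 0.00182, and adjusted p = 0.272 with an estimated correlation).

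S phase genes were higher in cotyledon uninucleate-like nuclei in 7 of 20 cases (13 adjusted over the list alone, camera adjusted p = 5.904e-05, and adjusted p = 0.443 with an estimated correlation). Within cluster 1 the list's adjusted p was 0.135. MCM7 (ENSBTAG00000030965) averaged 467 ± 179 against 94.6 ± 26.7 CPM, with an edgeR Benjamini-Hochberg adjusted p of 0.0249, which was 0.0582 without cotyledon replicate 2 and 0.0965 without intercotyledonary replicate 2, the highest over 18 alternatives. G2 and M phase genes had 3 of 20 higher in the cotyledon and 1 lower (3 and 1 adjusted over the list alone, adjusted p = 0.0405, and adjusted p = 0.643 with an estimated correlation). The list's adjusted p was 0.0581 with the free RNA profile subtracted and 0.366 within cluster 1. Transporters had 13 of 29 higher in the intercotyledonary placenta and 4 in the cotyledon (15 and 6 adjusted over the list alone, adjusted p = 0.0199, and adjusted p = 0.416 with an estimated correlation), among them the amino acid transporter subunit SLC3A2 at 137 ± 43.8 against 684 ± 42.4 CPM. The transporter list had an adjusted p of 0.419 within cluster 1. Of the imprinted and insulin-like growth factor genes 9 of 20 were higher there and 3 in the cotyledon, with no call for the list (adjusted p = 0.126). Of the transcription factors 4 of 18 were higher there, with MSX2 at 16.2 ± 2.36 against 71.3 ± 2.36 CPM, and 2 in the cotyledon, among them GCM1 (list adjusted p = 0.195). Prostaglandin, steroid and hypoxia genes went both ways without a list call, with 4 of 10, 2 of 15 and 2 of 15 higher in the intercotyledonary placenta and 1, 2 and 2 in the cotyledon (adjusted p = 0.143, 0.756 and 0.335). Within cluster 1 the steroid list was called, higher in the cotyledon (adjusted p = 2.992e-05 at the preset correlation). EGLN3, a hydroxylase that marks hypoxia factors for decay, averaged 4.14 ± 2.7 against 102 ± 14.8 CPM. Both trophoblast Kunitz genes tested were higher in the intercotyledonary placenta.

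Markers of other classes were seen in these sums as well. Of the binucleate markers 8 of 23 were higher in cotyledon uninucleate-like nuclei and 4 lower (10 and 5 adjusted over the list alone, camera adjusted p = 0.0405, and adjusted p = 0.643 with an estimated correlation), and PAG7 averaged 601 ± 503 against 28.5 ± 19.3 CPM beside 188 CPM in the pooled other types of the cotyledon. PAG6 and PAG9 also lay above those types in both cotyledon samples. PAG17 lay below them, at 207.3 and 399.3 CPM beside 233.8 and 732.6, so some of these levels may be background. Within cluster 1 the binucleate marker list and the mesenchyme list each had an adjusted p of 0.0652. Of the mesenchyme markers 2 of 5 were higher in the intercotyledonary placenta (3 adjusted over the list alone, adjusted p = 0.0199, and adjusted p = 0.512 with an estimated correlation), and of the epithelium markers 3 of 5 (adjusted p = 0.143). Of the macrophage markers 2 of 6 were higher in the cotyledon and 1 lower (adjusted p = 0.143), of the endothelium markers 2 of 4, of the erythroid markers 1 of 3, and of the endometrium markers 1 of 4 each way. None of the 3 pericyte markers passed by edgeR.

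**Figure D2:**
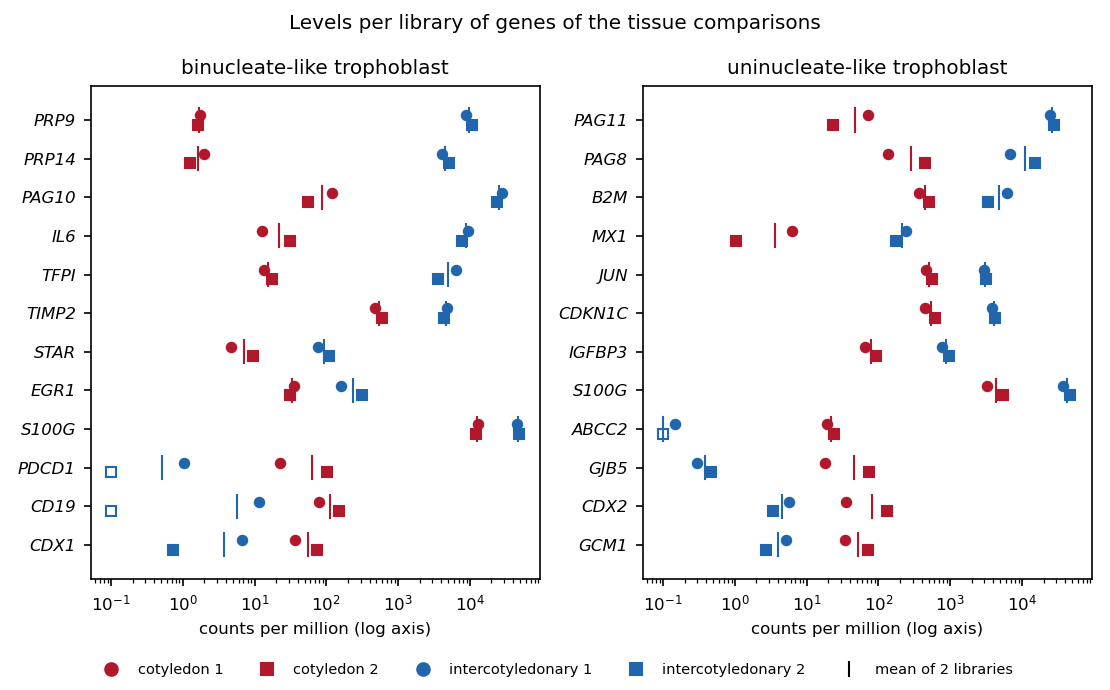
CPM (log axis) of 12 genes in binucleate-like and 12 in uninucleate-like trophoblast, with 1 circle for replicate 1, 1 square for replicate 2 and a bar for the mean of each tissue. Open marks at 0.1 stand for 0 counts, and every gene shown had both samples of 1 tissue above both of the other.

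**Figure D3:**
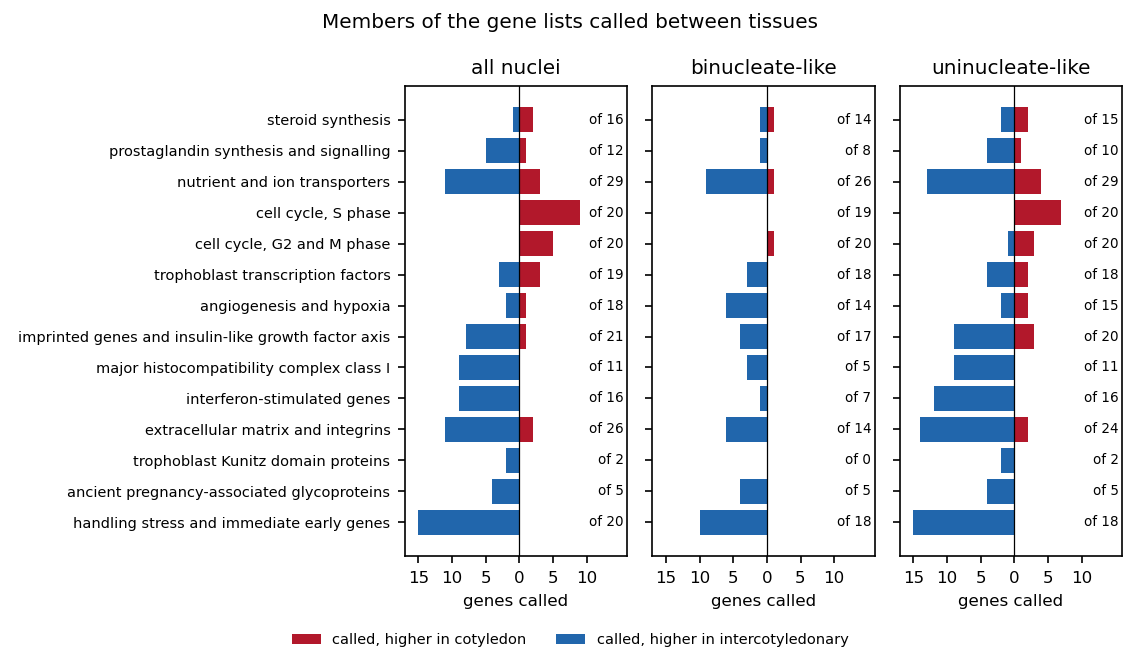
Number of members of each fixed gene list (horizontal axis) that passed the test in each tissue comparison, drawn to the right where higher in the cotyledon and to the left where higher in the intercotyledonary placenta, with the number tested at the right edge. Handling stress genes passed 15 of 20 over all nuclei, 10 of 18 in binucleate-like and 15 of 18 in uninucleate-like trophoblast, all higher in the intercotyledonary placenta.

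The tissue difference itself differed between the trophoblast classes for many genes. Both classes were made up of different clusters in the cotyledon and the intercotyledonary placenta. Cluster 10 held 15.8% and 87.6% of the binucleate-like nuclei, and cluster 1 held 2.84% and 74.1% of the uninucleate-like ones. The interaction was not tested within single clusters, so it may set unlike cells against each other. TIMP2, TFPI and STAR had a lower ratio of cotyledon over intercotyledonary in binucleate-like than in uninucleate-like trophoblast, and so had the peptide hormone gene ADM, whose log2 ratio was -2.24 in the first and 0.34 in the second. The ratio was higher in binucleate-like trophoblast for B2M, SLC3A2 and the zinc and manganese transporter SLC39A8. The taurine transporter SLC6A6 went in opposite directions, higher in the cotyledon in binucleate-like nuclei (99.6 ± 2.88 against 16.3 ± 12.8 CPM) and lower in uninucleate-like nuclei. Within binucleate-like nuclei alone, its edgeR Benjamini-Hochberg adjusted p of 0.0313 was 0.0708 without cotyledon replicate 1 and 0.135 without cotyledon replicate 2, with 0.726, within cluster 10, the highest over 17 alternatives, and it leads cluster 13, which held 4 of the intercotyledonary nuclei of the class. ADM in that class had 0.0614 without cotyledon replicate 1, with 0.0988 the highest. CDX2 and GCM1, transcription factors of early and of differentiating trophoblast, had log2 ratios of 3.76 and 3.29 in uninucleate-like nuclei. In binucleate-like nuclei these were 0.25 and -0.01.

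With the sample as a block, edgeR with Benjamini-Hochberg adjustment called this difference in 1794 of 12852 genes, 1095 with a log2 ratio of cotyledon over intercotyledonary that was higher in binucleate-like trophoblast and 699 with a lower one. DESeq2 split its 1522 calls into 748 and 774, so 61.0% against 49.2% were higher, and the direction of the whole set is not read. The median over all genes tested was 0.19 with TMM and 0.08 with DESeq2's size factors, a shift of -0.11, so gene values are given relative to that median. They were -3.13 for TIMP2, -4.38 for TFPI, -4.12 for STAR, -2.73 for ADM, 3.23 for B2M, 2.34 for SLC3A2, 3.65 for SLC39A8, 4.07 for SLC6A6, -3.31 for CDX2 and -3.27 for GCM1 (log2). Whether TFPI in uninucleate-like nuclei is background was not judged, so its value may not be exact. Of the fixed lists, the binucleate markers had 21 of 23 members with a lower value in binucleate-like trophoblast (some stood no higher in uninucleate-like nuclei than in the pooled other cell types), the stress genes 9 of 18 with a higher one, and the transporters 12 of 29 higher and 7 lower. The binucleate markers named that class and were not kept out of clustering, so nothing is concluded from their count. The count was 1113 without intercotyledonary replicate 2 and 1106 with counts thinned to the smallest sample. Called in both classes with the same direction were 33 genes higher in the cotyledon (5.1 if the lists were independent) and 364 higher in the intercotyledonary placenta (71.1 if independent), but both comparisons use the same 4 samples.

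Between the classes, within each sample, 15 of 20 S phase genes were higher in binucleate-like than in uninucleate-like nuclei, and 14 of 21 imprinted, 15 of 16 interferon-stimulated and 8 of 11 prostaglandin genes were lower. MCM7 averaged 1096 ± 201 CPM in binucleate-like and 281 ± 239 in uninucleate-like nuclei (SD over 4 samples), and PPARG (ENSBTAG00000001333), a nuclear receptor of trophoblast differentiation, 356 ± 56.9 against 107 ± 61.1. CDKN1C averaged 84.4 ± 70.1 against 2293 ± 2036 CPM, and PTGES (ENSBTAG00000019453), a prostaglandin E synthase, 1.36 ± 0.767 against 33.1 ± 21.9. CYP11A1 (ENSBTAG00000006934), the enzyme that starts steroid synthesis from cholesterol, averaged 11.8 ± 3.72 against 193 ± 115 CPM. Only the 228 tested genes of the fixed lists that were kept out of clustering are compared here. This does not make them independent of the classes, since genes that vary with them still shaped the clusters. Binucleate-like cluster 4 has CCNB2 and PLK1, of the G2 and M phase list, among its leading genes. The p-values between classes may therefore be too small. Of these 126 passed edgeR with Benjamini-Hochberg adjustment, 39 higher and 87 lower in binucleate-like trophoblast.

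Of the S phase genes 15 of 20 were higher and 1 lower in binucleate-like nuclei (15 and 1 adjusted over the list alone, camera adjusted p = 2.187e-05, and adjusted p = 0.384 with an estimated correlation). For MCM7 the log2 ratio of binucleate-like over uninucleate-like was 2.74 ± 0.5 (SE, adjusted p = 0.00294 by edgeR with Benjamini-Hochberg), higher in 4 of 4 samples. G2 and M phase genes had 7 of 20 higher and 2 lower (7 and 2 adjusted over the list alone, adjusted p = 0.0203, and adjusted p = 0.527 with an estimated correlation). Of the transcription factors 6 of 18 were higher and 2 lower (adjusted p = 0.152), among them PPARG with a log2 ratio of 2.22 ± 0.28, higher in 4 of 4 samples (edgeR Benjamini-Hochberg adjusted p = 0.000806). Angiogenesis and hypoxia genes went both ways, 4 higher and 5 lower of 16 (adjusted p = 0.26), with ADM at 292 ± 202 against 39.1 ± 15.1 CPM and EPAS1, a hypoxia-inducible factor, at 15.9 ± 9.03 against 173 ± 120.

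Interferon-stimulated genes were lower in binucleate-like nuclei in 15 of 16 cases (15 adjusted over the list alone, camera adjusted p = 2.187e-05, and adjusted p = 0.243 with an estimated correlation). Imprinted and insulin-like growth factor genes were lower in 14 of 21 and higher in 2 (14 and 2 adjusted over the list alone, adjusted p = 0.000158, and adjusted p = 0.233 with an estimated correlation). Prostaglandin genes were lower in 8 of 11 (8 adjusted over the list alone, adjusted p = 0.00212, and adjusted p = 0.233 with an estimated correlation). Ancient PAGs were lower in 4 of 5 and higher in 1, which was PAG10 (4 and 1 adjusted over the list alone, adjusted p = 0.00274, and adjusted p = 0.233 with an estimated correlation). Extracellular matrix genes were lower in 9 of 26 and higher in 1 (9 and 1 adjusted over the list alone, adjusted p = 0.00692, and adjusted p = 0.243 with an estimated correlation), the 1 being TIMP2 with 2567 ± 2343 against 140 ± 33.4 CPM. Stress genes were lower in 8 of 18 (8 adjusted over the list alone, adjusted p = 0.0203, and adjusted p = 0.527 with an estimated correlation). Without a list call, MHC class I genes were lower in 4 of 11 (adjusted p = 0.136), transporters lower in 8 of 29 and higher in 1 (0.0704), and steroid synthesis genes lower in 5 of 15 and higher in 2 (0.236). Without the sample as a block, 4 of the list calls between the classes were lost, those of the ancient PAGs (adjusted p = 0.0942), the extracellular matrix and the G2 and M phase genes (0.0856 each) and the stress genes (0.119). Both trophoblast Kunitz genes tested were lower. The calcium channel TRPV6 averaged 5.61 ± 2.96 CPM in binucleate-like and 104 ± 88.0 in uninucleate-like nuclei.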

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

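For 1794 genes the difference between the tissues was itself different between binucleate-like and uninucleate-like trophoblast (edgeR test of the interaction, Benjamini-Hochberg). Different clusters made up both classes in each tissue, so these differences may set unlike cells against each other. For 463 of the genes, both samples of 1 tissue had a higher CPM than both of the other in 1 class and a lower one in the other class. That separation needs no passing test in either class, so 463 is not read as a count of reversals. The named genes among the 1794 follow. Each has the log2 ratio of cotyledon over intercotyledonary in binucleate-like minus that in uninucleate-like trophoblast, relative to the median gene. Lower values were seen for hormone and glycoprotein genes, PRP-VII -5.14, PRP9 -4.17, PAG10 -3.92, PRP1 -3.72, PRP2 -3.41, PAG7 -3.21, PAG6 -2.59, PAG17 -2.28 and PAG9 -2.2. In intercotyledonary uninucleate-like nuclei PRP-VII, PRP9, PRP1, PRP2, PAG10 and PAG17 stood no higher than the 95% counting interval of the pooled endothelium-like, macrophage-like and lymphocyte-like nuclei in either sample, with PRP9 at 213.5 and 65.56 CPM beside 442.9 and 60.69. Their levels in that class are read as background there, and the difference between the classes is not exact. PRP9, PRP1, PRP2, PAG7, PAG6, PAG17 and PAG9 are also among the markers that named binucleate-like trophoblast, so their values may be partly set by that naming. Lower values were also seen for LSAMP -6.21, EMX2 -5.21, CRISPLD2 -4.95, NRN1 -4.46, TFPI -4.38, STAR -4.12, MCEMP1 -3.76, FMO2 -3.48, SEC14L2 -3.46, HHIP -3.4, CDX2 -3.31, GCM1 -3.27, TIMP2 -3.13, ADM -2.73, CA9 -2.62, IL6 -2.6, MCM7 -2.32, PDK1 -2.32 and MCM5 -1.12.

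Higher values were seen for transporters, SLC6A6 4.07, SLC39A8 3.65, SLC7A8 2.37, SLC3A2 2.34 and SLC40A1 1.11, and for genes of antigen presentation and interferon response, B2M 3.23, IFIH1 2.29 and TAPBP 1.16. STRA6 6.71, UPK1B 4.68 and TKDP4 3.14 had too few counts to be tested in binucleate-like trophoblast, so these values are not exact. Higher values were also seen for COL3A1 3.52, PTGDS 3.16, CD14 3.04, MSX2 1.75, JUND 1.74, NDRG1 1.38, PEG3 1.35, KIF23 1.25, CYP11A1 1.19, KLF6 1.16, ELF3 1.12, EPCAM 1.04, HSD3B1 1.02 and LAMC1 0.85. Mitochondrial genes were outside every comparison, yet they gave 15.999% and 7.6% of the UMIs of kept nuclei in cotyledon replicates 1 and 2 and 25.2% and 15.512% in intercotyledonary replicates 1 and 2. Where this RNA came from was not tested.

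Of the tests below, those of free RNA for the first 2 patterns and the splits of the sums were chosen after the result was seen. Genes higher in intercotyledonary binucleate-like trophoblast could come from the different clusters that make up the class. Within cluster 10 their median log2 ratio was -1.37 (588 genes, quartiles -2.25 and -0.56) beside -1.98 over the class, and 378 lay below -1. The genes were chosen from the same nuclei, and cluster 10 held 87.6% of the intercotyledonary nuclei of the class. It may also join unlike cells of the 2 tissues, so the make-up of the class is not excluded as the cause. After the free RNA profile was subtracted the median was -2.13 for 597 genes, so free RNA as estimated does not account for the difference. That estimate takes every mitochondrial UMI as free RNA, which was not tested, so free RNA is not excluded. Counts shared only among the 10 prolactin-related genes and CSH2 that were summed would leave their sum unchanged, but it differed by a log2 ratio of -2.84. Reads lost for matching several copies, or counted for copies without a symbol, could not be examined. A biological difference between the tissues remains open and was not tested further.

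Stress and immediate early genes were higher in the intercotyledonary placenta. The difference stayed within 1 cluster and after the free RNA profile was subtracted, an estimate with the limit given above. The list had a median log2 ratio of -2.75 within the cycling uninucleate-like cluster, and -2.87 over all nuclei after the free RNA profile was subtracted, beside -2.93 before. A response to handling should reach every cell type of a sample, and the medians were -1.78 in endothelium-like, -3.84 in macrophage-like and -1.64 in lymphocyte-like nuclei, the last being the highest of the 3. These are sums over 14 and 21, 7 and 53, and 27 and 29 nuclei in intercotyledonary replicates 1 and 2, too few for a test of each gene, and free RNA was not subtracted from them. That is consistent with handling, or with a state shared by all cells of the intercotyledonary samples, and a biological cause was not tested.

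The proton pump cluster 0 took 49.2% of the nuclei of cotyledon replicate 1 and 47.1% of the 5901 nuclei there with at least 2000 UMIs. The median depth of the cluster, relative to that of each sample, was 0.88. Of the 1384 nuclei of cotyledon replicate 1 with at least 5000 UMIs, the cluster held 2.31% (95% interval 1.59 to 3.25%). The share at 5000 UMIs is what low depth in that sample would give, but a minimum of 2000 UMIs changed the share little. In cotyledon replicate 2 the cluster held 15.1% of the nuclei with at least 5000 UMIs, so depth is not all of it. Of the 180444 UMIs of its leading genes in the cluster, 0.93% was predicted from the free RNA profile. These genes were chosen for the largest fold over other nuclei, which itself favours a low share, so nothing is concluded from this. Whether these are small nuclei of a real cell type was not tested.

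The 8 sums of the class comparison pair by sample, and 8 splits into 4 and 4 part the sums of every sample. Of these 1, the real one, called as many as 126 of the genes held out of clustering. The highest of the other 7 called 0 by edgeR, with at most 20 at an unadjusted p under 0.05. With 8 such splits no share under 0.05 can be had.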

How the results depend on the processing

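The limits on mitochondrial share, the subtraction of free RNA and the comparisons within single clusters or without the epithelium-like class were chosen after seeing the data. Leaving out 1 sample assumes that the lone sample of its tissue varies like the pair of the other. Except where a reason is given, the cause was not tested.

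Over all nuclei, 9 of 16 alternatives kept the count of 2212 genes within 1.5 times, from 1867 to 3020. DESeq2's Wald test gave 3485, no filter 4052, the replicate block 1332, a mitochondrial limit at 0.25 of the free RNA share 982, and leaving out 1 sample 346 to 2613. With the planned mitochondrial limit the edgeR count was 0, with 1540 genes at an unadjusted p under 0.05, where 5 barcodes were left in intercotyledonary replicate 1. The replicate block was fitted because samples share only a number: deviations of samples with the same number correlated by -0.042 over all nuclei, 0.187 in binucleate-like and 0.28 in uninucleate-like trophoblast, and nothing in the labels says that they are paired. In binucleate-like trophoblast 11 of 17 alternatives gave 485 to 985 genes beside 665, while no filter gave 1398, resolution 0.2 1308, the 0.25 limit 403 and leaving out 1 sample 259 to 1466. In uninucleate-like trophoblast 16 of 18 gave 2180 to 4221 beside 2957, with 1306 in the PAG11-led cluster and 1851 in the cycling cluster alone, which hold fewer nuclei and fewer tested genes. Leaving out 1 sample gave 2180 to 2765.

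The interaction count of 1794 was 1259 to 2222 in 13 of 15 alternatives, 1106 with thinned counts, where fewer genes were tested, and 1113 to 1630 with 1 sample left out. The class difference kept 103 to 136 genes in 15 of 16 alternatives beside 126, 114 to 127 with 1 sample left out, and 61 with no sample block.

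The share of binucleate-like nuclei was 10.16 points higher in the cotyledon, 21.74 with a minimum set per sample, 17.19 without integration, 17.63 at the 0.25 limit, -1.8 at resolution 0.2 and 3.67 to 16.65 with 1 sample left out. That of epithelium-like nuclei was -36.69 to -6.15 with 1 sample left out. The lymphocyte-like difference was -0.9 at 2000 UMIs and 0.0 with a minimum set per sample and at the 0.25 limit, and the macrophage-like one -2.54, -3.98 and -3.14 in the same order. With an estimated correlation 0 lists were called by camera in every comparison. Within cluster 10, 6 of 11 lists were called, within the PAG11-led cluster 7 of 17, and between classes without the sample block 4 of 13.

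Over named genes and alternatives, 4440 results stayed the same, 546 were weaker, 31 stronger, 11 moved and 1 reversed. The reversed one was PAG10 in uninucleate-like trophoblast, with a fitted log2 ratio of 10.55 after the free RNA profile was subtracted (edgeR Benjamini-Hochberg adjusted p = 0.00535). The subtraction removed all of its intercotyledonary counts, so the ratio is a bound, at least 129-fold against a floor of 3 counts. Over list tests 185 stayed the same, 63 were weaker, 2 stronger and 3 moved. With the replicate block the imprinted list in binucleate-like (adjusted p = 0.0855) and the binucleate marker list in uninucleate-like trophoblast (0.114) lost their camera calls, and the epithelium marker list over all nuclei gained one (0.0137, and adjusted p = 0.662 with an estimated correlation). The block split the 978 genes of binucleate-like trophoblast into 199 higher in the cotyledon and 779 lower. The alternatives for mesenchyme-like nuclei were not run, since some samples had fewer than 30. Depth may limit the binucleate-like comparison, which has 1930464 and 1377372 UMIs in the intercotyledonary sums.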
